A study of Mus musculus with 3 samples.

How the data were processed

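The material was whole testis of F1 males from a cross of C57BL/6J (B6) with CAST/EiJ (CAST), inbred strains that differ at many single bases, so that reads can often be assigned to the homologue they came from. PRDM9 is the zinc-finger protein that binds DNA motifs in meiotic cells, marks the flanking nucleosomes with H3K4me3 and so places double-strand breaks. Per the labels, these animals carried the CAST allele of Prdm9 together with a humanized allele (HUM). The series holds 3 libraries, 1 of each kind. DMC1 ChIP-seq captures the single-stranded DNA that the recombinase DMC1 coats at breaks under repair, and was made from a 10-week-old male. The H3K4me3 ChIP-seq and the MNase-seq libraries were made from micrococcal nuclease digested chromatin of an adult male. The MNase-seq library was not analysed here, since none of the values used here is labelled as coming from it. Whether it entered the authors' H3K4me3 values was not established.

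Per the submitters' processing notes, reads were aligned to mm10 with BWA, version 0.7.15 for the H3K4me3 and MNase libraries. For the DMC1 library the version is not given in the sources used here. The deposited table has 1 line per DMC1 hotspot, here called a site. Per the file headers, the site's position is the centre of a DMC1 peak and its DMC1 signal (the authors' "heat") is an intensity estimated by their peak caller. The H3K4me3 signal is the authors' estimate of enrichment at the same site. At 10220 of the 24586 sites its value repeats that of an earlier site. The headers credit the raw H3K4me3 reads to an earlier study by Li and colleagues, and do not state whether these are the reads of the H3K4me3 library of this series. How either signal was scaled to sequencing depth is not given in the sources used here, so the signals are in the authors' units and the ratio of DMC1 to H3K4me3 has no absolute meaning; it was compared only between sites. Per the file headers, the B6 fraction of each mark is the signal on the B6 homologue divided by the signal on both homologues; it is called the B6 share below. The headers also give the PRDM9 variant that the authors inferred for each site, and whether the site overlaps an H3K4me3 peak that does not depend on PRDM9. The classes are written CAST, HUM, UNK and KO; the headers do not define UNK and KO, and no meaning was assumed for them. The number of reads behind a signal or a share was unknown, so no counting error could be given for a single site, and a minimum of reads for a share could not be applied.

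Sites were grouped by PRDM9 class, by chromosome and by B6 share. A site was called one-homologue when its H3K4me3 B6 share was under 0.1 (CAST-only) or over 0.9 (B6-only), and both-homologue when the share was 0.3 to 0.7. Autosomes were the main set. X sites were taken outside the pseudoautosomal region of the reference X, the part shared with the Y. Its boundary, inside Mid1, was taken from general knowledge of the mouse X and not from the files or the annotation, so the division of sites there rests on it. Values were compared on the log2 scale with no pseudocount, since neither mark held a zero. The list of alternatives had named a pseudocount set from the smallest value (3.75 for DMC1 and 0.0851 for H3K4me3) as the starting point; that version was run as an alternative. Medians of classes were compared by their difference. Because there is 1 library per assay, sites are not replicates of an animal or a library, and no p-value was computed across sites. Unless stated otherwise, the 95% intervals come from a bootstrap over blocks of 5 Mb with 2000 draws, or 500 draws for the alternatives. They describe the variation among sites of these libraries, not among animals. The direction of each difference was also counted over the 19 autosomes taken one at a time. Differences at matched H3K4me3 were medians within 20 equal bins of H3K4me3, counted where both classes had at least 5 sites and weighted by the smaller class. Fewer bins were used for B6-only against CAST-only sites. The smaller classes, which were the X, KO and 3 classes of one-homologue sites, were also set against 10000 random sets of the same size and the same H3K4me3 bins. Shares of sites have exact Clopper-Pearson binomial intervals, which cover counting error only.

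Gene positions came from the RefSeq annotation of GRCm38.p6, the same build as mm10, with 21627 protein-coding genes on the autosomes and X. It gave gene starts and ends without strand or exons, so a site is described as inside a gene or between genes, and neither distance to transcription starts nor exon and intron could be assigned. A count of sites inside genes by class was added in place of the distance to transcription starts. A search for the human PRDM9 motif had been planned, needs the genome sequence and was not run. The 6 gene lists were fixed before the data were examined and all 76 of their symbols were matched, by symbol or synonym. Sites in the gene bodies with 5 kb flanks were compared with 10000 random lists, in which each gene was replaced by 1 of the 40 genes nearest to it in length. This matching was chosen after coarser bins of length had put the list of long genes at percentile 99.96 of its random lists. Sites named in the text were fixed by rule before the data were examined. The rule takes the 5 strongest DMC1 sites of each PRDM9 allele on autosomes and the 5 strongest X sites. It also takes the 3 highest and 3 lowest ratios among the stronger autosomal sites by summed ranks. From the 200 strongest sites it takes the 3 most B6-biased and the 3 most CAST-biased. It adds the strongest site of each gene list and up to 5 pseudoautosomal sites. The 200 were limited to autosomes when the rule was applied, which the rule did not state. With X sites included, other sites would have been the most B6-biased. Other genes of the lists and Mid1 were named after their values were seen. The excess of B6-only sites was taken from the DMC1 share, except where H3K4me3 is named. This excess, the sites inside genes and the distal X were taken up after the data were examined.

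Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The procedures were tested on simulated data laid over the real sites, with 100 simulations each and 200 bootstrap draws. For the difference of medians between CAST and HUM over 21653 sites, a true shift of 0.3 was estimated as 0.30 on average, and 94% of intervals held it; with no shift, 92% of intervals held 0. For the difference at matched H3K4me3 over 15523 sites, 97% of intervals held a shift of 0.3 and 92% held 0. For the rank correlation over 23631 sites, 92% of intervals held the true value. Of 200 random lists of 20 genes, 9.5% fell outside the central 95% of their matched lists, so the percentiles of gene lists are somewhat too extreme. Of 200 random sets of 900 autosomal sites, 5% did. Alternatives covered the pseudocount, the mean in place of the median, filters on low signal, other limits on the B6 share, sites that overlap PRDM9-independent peaks, and each chromosome left out in turn.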

Results

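The table held 24586 DMC1 sites, 23631 on the 19 autosomes and 955 on the X, with a median spacing of 56.8 kb. The median DMC1 signal was 62.1 (quartiles 25.9 and 171) and the median H3K4me3 enrichment 11.6 (quartiles 6.10 and 22.8), each in the authors' units. A B6 share was given for DMC1 at 91.9% of sites and for H3K4me3 at 92.6%. There was 1 library per assay, so no difference below has a replicate check, and the depth of the libraries was unknown.

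The first question was how the sites divide between the 2 PRDM9 alleles of the animal. The CAST allele had 12908 sites, 52.5% of all (exact 95% interval 51.9% to 53.1%), and the humanized allele had 9605, or 39.1% (38.5% to 39.7%). A further 1989 sites were of class UNK and 84 of class KO. On autosomes the CAST sites carried 64.5% of the summed DMC1 signal and the HUM sites 30.9%, a wider gap than in their numbers. Among the stronger 50% of sites by DMC1, the CAST share was 60.2% (59.3% to 61.1%). Overlap with PRDM9-independent H3K4me3 was low at CAST sites (7.79% of 12372 autosomal sites) and HUM sites (7.28% of 9281), higher at UNK sites (18.9%), and 77.4% at the 62 autosomal KO sites.

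Sites of the CAST allele were stronger in both marks. The median DMC1 signal on autosomes was 82.7 at CAST sites and 52.0 at HUM sites, a difference of 0.67 on the log2 scale (95% interval 0.60 to 0.74), or 1.59-fold. H3K4me3 enrichment differed less, with medians of 13.2 and 10.5, a log2 difference of 0.33 (0.29 to 0.38) or 1.26-fold, and of 0.21 (0.18 to 0.25) between means of log2 values. CAST sites thus also had more DMC1 for their H3K4me3, with a log2 ratio higher by 0.36 (0.32 to 0.39) or 1.28-fold. At matched H3K4me3 the difference in log2 DMC1 was 0.32 (0.29 to 0.36). All 3 differences had the same direction on 19 of 19 autosomes, although the difference in H3K4me3 came down to 0.02 on chromosome 3.

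**Figure D1:**
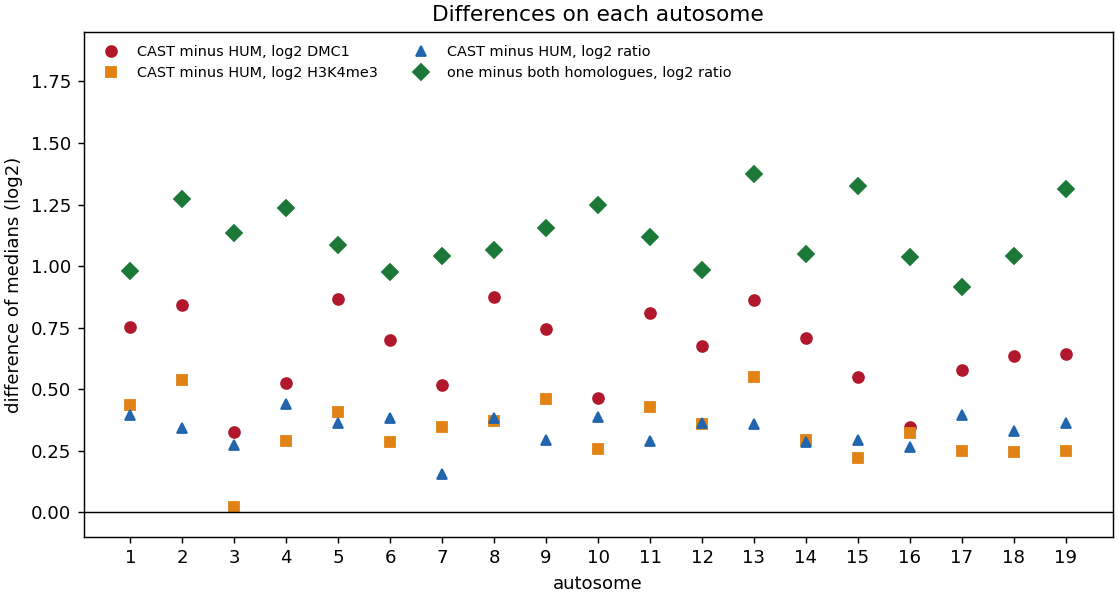
Difference of medians on the log2 scale (vertical axis) on each of the 19 autosomes (horizontal axis), for CAST minus HUM sites in DMC1, H3K4me3 and their ratio, and for one-homologue minus both-homologue sites in the ratio. Each point is 1 chromosome, and all points lie above 0, those for DMC1 between 0.32 and 0.87 and those for one minus both homologues between 0.91 and 1.37.

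The strongest CAST site on autosomes, at chromosome 3 position 83078979 (mm10), lay 6.69 kb outside Plrg1, with DMC1 1139 and H3K4me3 36.5. The next lay inside Bach2, which encodes a transcription factor of lymphocytes (chromosome 4, 32573877; DMC1 1128), and inside Usp6nl (chromosome 2, 6409938; DMC1 1106). Both were used on both homologues, with DMC1 B6 shares of 0.436 and 0.50. The fourth, inside Gdf6, a growth factor of joint development (chromosome 4, 9851229; DMC1 1093), and the fifth, between genes 92.1 kb from Lhfp (chromosome 3, 53353790; DMC1 1052), were almost entirely on the B6 homologue, with shares of 0.991 and 0.995. Among HUM sites the strongest lay 4.21 kb from Phtf2 (chromosome 5, 20754459; DMC1 1202). It was followed by sites inside Cfap54, a gene of the ciliary axoneme (chromosome 10, 93007642; DMC1 1100), Kdm3b, a histone demethylase (chromosome 18, 34810512; DMC1 1044), and Slc26a4, an anion transporter (chromosome 12, 31533758; DMC1 947). The last of these 5 lay 158 kb from Cited2 (chromosome 10, 17565264; DMC1 941). The site in Cfap54 had a B6 share of 0.998, and the other 4 had shares of 0.334 to 0.622.

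How far DMC1 follows H3K4me3 was asked across sites. Over 23631 autosomal sites the Spearman correlation was 0.714 (95% interval 0.706 to 0.723), and between 0.691 and 0.767 on single autosomes. It was higher at CAST sites (0.741, interval 0.731 to 0.751) than at HUM sites (0.673, 0.660 to 0.687). At the 2050 autosomal sites that overlap a PRDM9-independent H3K4me3 peak it was 0.381 (0.342 to 0.423), and at the other 21581 it was 0.770 (0.762 to 0.777). On the X it was 0.750 (0.668 to 0.817, 946 sites). The median DMC1 signal rose from 17.3 in the lowest 10% of sites by H3K4me3 to 287 in the highest 10%. These correlations are across sites of single libraries, and sites are not independent replicates. Every site is a DMC1 peak, so places with H3K4me3 but no called DMC1 peak enter neither the correlations nor the ratios.

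**Figure D2:**
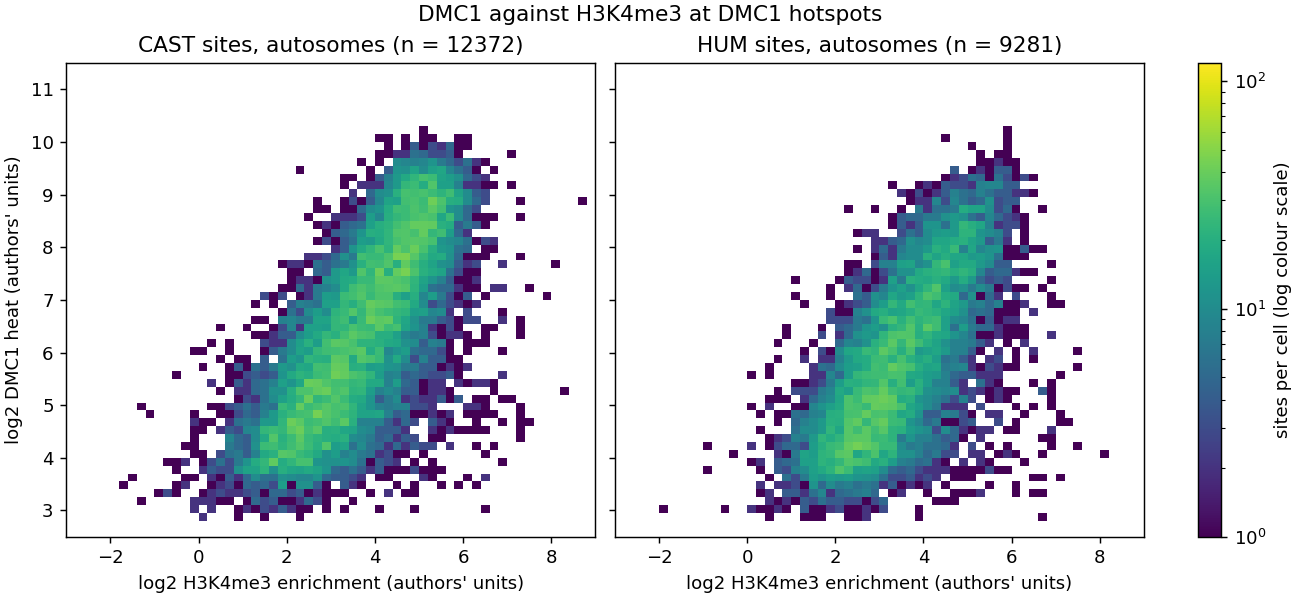
Number of autosomal sites (colour, log scale) by log2 H3K4me3 enrichment (horizontal axis) and log2 DMC1 signal (vertical axis), both in the authors' units, for 12372 CAST sites and 9281 HUM sites. Both clouds rise together, with Spearman correlations of 0.741 and 0.673, and a thin group of sites with high H3K4me3 and low DMC1 lies below each.

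The sites that left this trend were of different kinds at its ends. The 3 highest ratios among the stronger autosomal sites were all on the CAST homologue. They lay 58.2 kb from Tcim (chromosome 8, 24379008, CAST class, 146 times as much DMC1 as H3K4me3 in the authors' units, DMC1 B6 share 0.0103), inside Nck2, an adaptor of receptor signalling (chromosome 1, 43462065, HUM, ratio 78.7), and 22.6 kb from Atg4c, an autophagy protease (chromosome 4, 99166587, CAST, ratio 72.4). Their DMC1 was 696, 409 and 445, but their H3K4me3 was only 4.77, 5.19 and 6.15, near or under the lower quartile of 6.10. They passed the rule on summed ranks through DMC1, and their ratios rest on low H3K4me3. The 3 lowest were UNK sites that overlapped PRDM9-independent H3K4me3. They lay inside Ppp4r4 (chromosome 12, 103533268; DMC1 14.2, H3K4me3 340), 0.933 kb from Tmco1 (chromosome 1, 167307737; DMC1 17.8, H3K4me3 348) and inside Nup205, a nuclear pore component (chromosome 6, 35178065; DMC1 16.4, H3K4me3 308). Each of these 3 was within about 1 kb of an annotated end of the gene.

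Because the animal is a hybrid, each site can be used on the B6 homologue, the CAST homologue or both. At CAST sites DMC1 was skewed to the B6 homologue: 21.3% of 11629 sites had a DMC1 B6 share over 0.9 and 10.2% had one under 0.1, an excess of 11.1 percentage points (95% interval 10.1 to 12.2). At HUM sites the corresponding shares were 17.2% and 18.8% of 8567 sites, an excess of -1.67 points (-2.98 to -0.25). The difference between the alleles was 12.8 points (10.98 to 14.5) and had the same direction on 19 of 19 autosomes. H3K4me3 gave 10.9% and 3.60% at CAST sites and 7.24% and 6.58% at HUM sites, a difference of 6.62 points (5.55 to 7.68). The median DMC1 share was 0.496 at CAST sites and 0.442 at HUM sites, a difference of 0.054 (0.042 to 0.063), but 0.181 when sites were weighted by their DMC1 signal and means were compared. CAST sites with a DMC1 share over 0.9 had a median DMC1 of 188, against 70.5 at those with a share under 0.1, while HUM sites had 53.7 and 71.7.

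**Figure D3:**
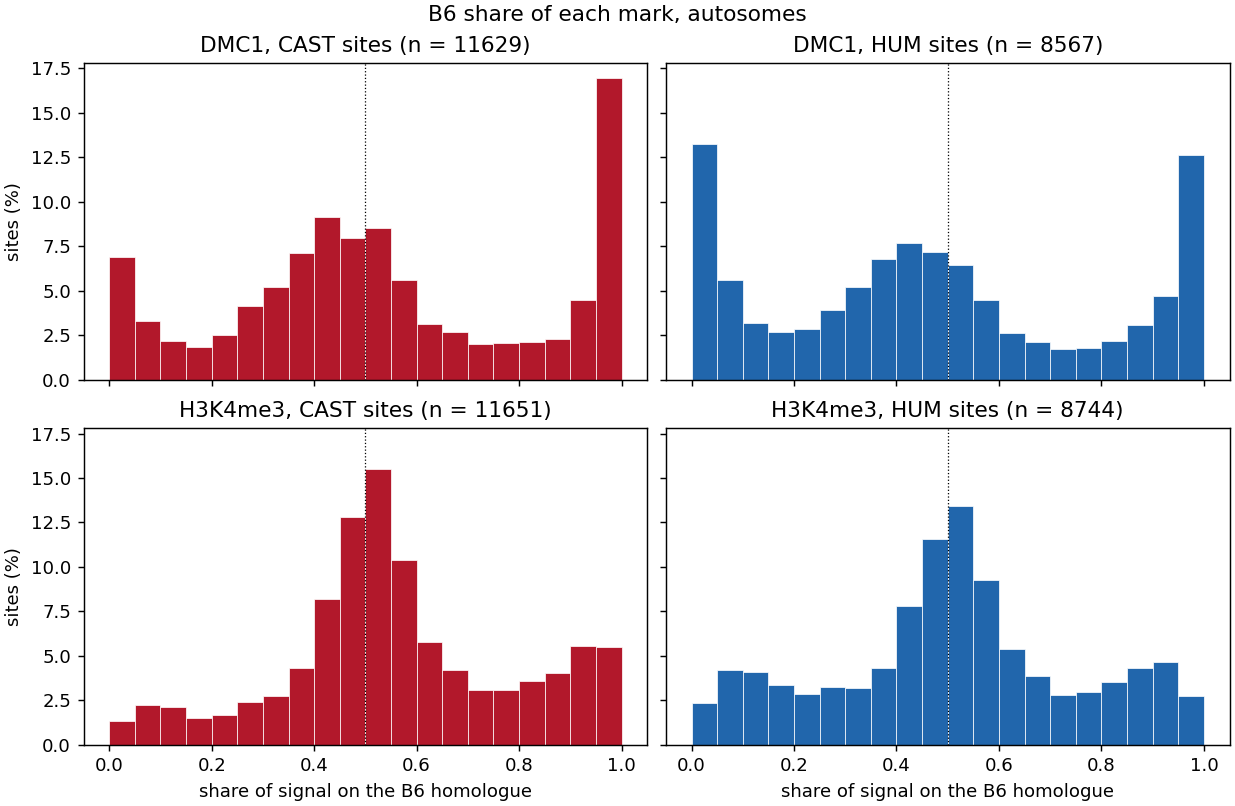
Percent of autosomal sites (vertical axis) by share of signal on the B6 homologue (horizontal axis, bins of 0.05), for DMC1 (upper row) and H3K4me3 (lower row) at CAST sites (left) and HUM sites (right). The DMC1 panels have peaks at both ends, uneven at CAST sites (21.3% over 0.9 and 10.2% under 0.1) and near even at HUM sites (17.2% and 18.8%), and the H3K4me3 panels have most sites between 0.3 and 0.7.

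Of the 200 strongest autosomal sites, 171 were CAST and 22 HUM, and of the 196 with a DMC1 share 98 were over 0.9, 5 under 0.1 and 69 between 0.3 and 0.7. The 3 most B6-biased were CAST sites, inside Brf2, a subunit of an RNA polymerase III factor (chromosome 8, 27126293; DMC1 share 0.999), inside Epha7, an ephrin receptor (chromosome 4, 28839987; 0.998), and 7.08 kb from Olfr1349, an olfactory receptor (chromosome 7, 6527430; 0.998). The 3 most CAST-biased were a CAST site inside Pbrm1, a chromatin remodeller (chromosome 14, 31054569; 0.00630), and HUM sites 7.94 kb from Rnf122 (chromosome 8, 31141258; 0.00758) and 86.0 kb from Mgst1 (chromosome 6, 138242734; 0.0138). The shares of the marks rose together across sites, with Spearman correlations of 0.832 at CAST sites and 0.854 at HUM sites, but they were offset. Where the H3K4me3 share was 0.45 to 0.55, the median DMC1 share was 0.451 (0.444 to 0.457) at CAST sites and 0.435 (0.429 to 0.441) at HUM sites, under 0.5 on 19 of 19 autosomes in both.

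Sites marked on 1 homologue had more DMC1 for their H3K4me3 than sites marked on both. The 2896 one-homologue sites had a median DMC1 of 154 and a median H3K4me3 of 13.3, and the 12627 both-homologue sites had 64.3 and 13.9. The log2 ratio was higher by 1.14 (95% interval 1.07 to 1.19), or 2.20-fold, and on 19 of 19 autosomes. The difference was 1.21 (1.16 to 1.26) at CAST sites and 0.95 (0.87 to 1.03) at HUM sites. By direction it was 1.24 at B6-only and 1.07 at CAST-only sites of the CAST allele, and 0.70 (0.60 to 0.83) at B6-only and 1.17 (1.06 to 1.29) at CAST-only sites of the HUM allele. The 420 CAST-only sites of the CAST allele and the 633 B6-only and 575 CAST-only sites of the HUM allele each exceeded all of 10000 random sets of both-homologue sites matched on H3K4me3. With the classes taken from the DMC1 share the difference was 0.77 (0.72 to 0.81).

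**Figure D4:**
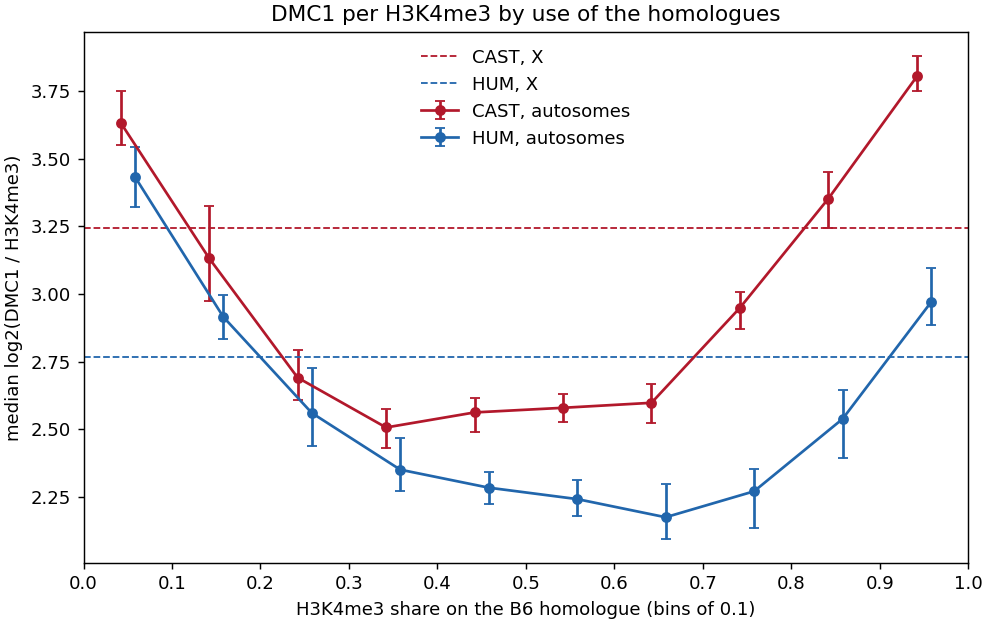
Median log2 ratio of DMC1 to H3K4me3 (vertical axis, not starting at 0) by H3K4me3 share on the B6 homologue in bins of 0.1 (horizontal axis), for autosomal CAST and HUM sites, with 95% block-bootstrap intervals; dashed lines are the medians of X sites. The CAST curve falls from 3.63 in the lowest bin to 2.51 and rises to 3.80 in the highest, and the HUM curve from 3.43 to 2.18 and to 2.97. The medians of X sites include sites without an H3K4me3 share.

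In males the X has no homologue outside the pseudoautosomal region. Its 946 sites there had a median DMC1 of 77.0 and a median H3K4me3 of 10.98, against 61.4 and 11.6 on autosomes. The log2 ratio was higher on the X by 0.41 (95% interval 0.23 to 0.63), or 1.33-fold, and above all of 10000 random autosomal sets matched on H3K4me3. The difference was 0.46 (0.19 to 0.63) at CAST sites and 0.33 (0.16 to 0.46) at HUM sites. Against one-homologue autosomal sites the direction turned, and the 859 X sites of both alleles were lower by 0.57 on the log2 scale (a difference of -0.57, interval -0.73 to -0.40). Against both-homologue sites they were higher by 0.57 (0.39 to 0.72). In these 2 comparisons every autosomal site had an H3K4me3 share, while X sites without it were kept, so the sets were not filtered alike. Without the last 1 Mb of the X the difference from all autosomal sites was 0.38 (0.20 to 0.47). The comparisons with one-homologue and both-homologue sites were not repeated without that part, where signal on the CAST homologue was found (below). The 5 strongest X sites had the highest DMC1 signals named here. The first, which was the maximum of the table, lay 10.8 kb from Gm36049 (position 161374554; H3K4me3 62.6). The others lay 40.8 kb from 4930402K13Rik (9147186; DMC1 1780), inside Ints6l (56486722; DMC1 1700), inside Gla, the lysosomal alpha-galactosidase (134595751; DMC1 1486), and 27.7 kb from Tmem255a (38280163; DMC1 1419). The first 4 were CAST sites with DMC1 B6 shares of 0.999 or more after rounding, and the fifth was UNK.

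Sites of the X were on the B6 homologue except near its end. Of the 730 X sites before position 169587972 with a DMC1 share, 2 had one under 0.9, and of 620 with an H3K4me3 share, 2 did. From that position to the last site at 170005227, a stretch of 417 kb, all 39 sites with a DMC1 share had one under 0.9, with a median of 0.0856 (1 of them lay in the pseudoautosomal part of the reference X), and 14 of 16 H3K4me3 shares were under 0.9. At the 16 sites with both shares the median was 0.494 for H3K4me3 and 0.135 for DMC1, and the DMC1 share was the lower at 13. The 7 of these that overlap a PRDM9-independent H3K4me3 peak had a median H3K4me3 share of 0.521, and the other 9 had 0.286 (from 0.0324 to 1). The stretch held 49 sites, spaced at a median of 4.53 kb against 75.2 kb on the rest of the X, and 43 of them lay inside Mid1, a ubiquitin ligase gene that spans the pseudoautosomal boundary of the reference X (169685199 to 169990798). Only 28.6% of them were CAST or HUM sites, against 93.4% before. Their median H3K4me3 was 1.76, against 11.7, while median DMC1 was 70.3, against 78.5. The pseudoautosomal part of the reference X had 9 sites; the 5 strongest were of class KO, in and 3.31 kb beyond Mid1, with DMC1 of 83.8 to 327 and H3K4me3 of 3.02 to 12.4.

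**Figure D5:**
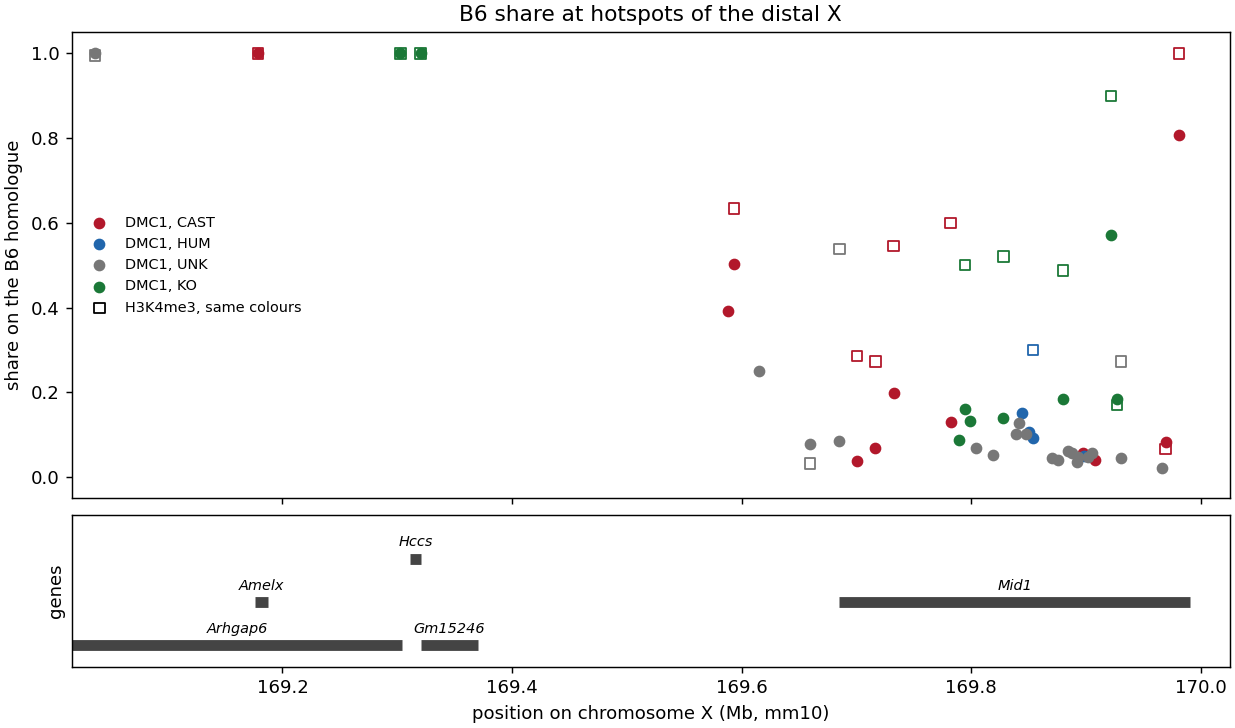
Share of DMC1 (filled circles) and H3K4me3 (open squares) on the B6 homologue (vertical axis) at sites in the last 1 Mb of the X by position in Mb (horizontal axis, mm10), coloured by class, with protein-coding genes below. Shares are at or near 1 up to Hccs and fall below 0.9 at all DMC1 sites from 169587972 on, most of them inside Mid1.

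Sites lay inside protein-coding genes more often than randomly placed positions did. Of the autosomal CAST sites 52.5% were inside a gene (51.6% to 53.4%), of the HUM sites 57.0% (56.0% to 58.0%), and of positions placed at random on the same chromosomes 41.2% on average, at most 42.0% in 100 placements. The CAST minus HUM difference was -4.50 percentage points (bootstrap interval -5.91 to -3.06). Of the 62 KO sites 16.1% were inside a gene (8.02% to 27.7%).

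None of the 6 gene lists fixed beforehand stood apart from random lists of similar gene length. The 27 genes of meiotic break formation and repair held 22 sites in 15 genes, at percentile 14.9 of the random lists. They included 4 sites in Mlh3, which acts in crossover formation, among them the strongest of the list (chromosome 12, 85247178; CAST, DMC1 513), 4 in Hsf2bp and 1 in Dmc1 itself (chromosome 15, 79588477; HUM, DMC1 55.4). No site lay in or near Spo11, which makes the breaks, Prdm9 or Brca2. The 13 genes of the chromosome axis and synaptonemal complex held 7 sites in 5 genes (percentile 27.2), 3 of them in Hormad2, an axis protein, with the strongest at chromosome 11 position 4407994 (CAST, DMC1 832). The 11 Sertoli and Leydig cell genes held 3 sites (percentile 19.3), near Sox9 and in Wt1 and Gata4, all of the HUM class, the strongest in Gata4 (chromosome 14, 63228527; DMC1 157). The 8 spermatid genes held 3 sites in 2 genes (percentile 81.5), the strongest 2.89 kb from Odf1, a gene of the sperm tail (chromosome 15, 38229628; CAST, DMC1 311). The 5 neighbours of classical mouse hotspots held 21 sites (percentile 66.1), and the strongest lay 1.87 kb from Psmb9, in the major histocompatibility region (chromosome 17, 34180162; CAST, DMC1 523, H3K4me3 71.7).

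The 12 long neuronal genes all held sites, 135 in total, with 18 in Macrod2, 16 each in Cntnap2, Ptprd and Dlg2 and 4 in Ctnna2. The strongest was in Nrxn3, a synaptic adhesion gene (chromosome 12, 90143937; CAST, DMC1 694, B6 share 0.994). The count was at percentile 78.5, but these genes are longer than their replacements, with 21398 kb in the list against 16491 kb on average. Per length they held 6.31 sites per Mb, at percentile 14.0 of the random lists. With random lists matched only in 50 coarse bins of length, the count stood at percentile 99.96.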

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

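Chosen after the results were seen were the test without sites that overlap PRDM9-independent peaks, the X against both-homologue sites, the test of mapping, the excess by H3K4me3, the differences between alleles in these effects, the tests on the distal X and the ratio of the KO class.

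The gain in DMC1 per H3K4me3 at one-homologue sites stood out because it differed between the PRDM9 alleles: it was larger at CAST than at HUM sites by 0.26 on the log2 scale (95% interval 0.17 to 0.34), and by 0.17 (0.07 to 0.27) at matched H3K4me3. Weak H3K4me3 would make the gain vanish at matched H3K4me3, where it was 1.15 (1.1 to 1.2), which argues against it as the whole cause. Called PRDM9-independent peaks as the whole cause would make the gain vanish without the overlapping sites, where it was 1.08 (1.02 to 1.13). The gain was thus present at sites without a called peak. Only 7.79% of CAST and 7.28% of HUM autosomal sites overlap such a peak. Leaving out so few sites can move a difference of medians only a little, so this outcome was close to fixed in advance. PRDM9-independent H3K4me3 too weak to be called as a peak was not removed, so its part was not tested. With the classes taken from the DMC1 share the gain was 0.77 (0.72 to 0.81). A hypothesis that DMC1 may stay longer, or breaks be more frequent, where no marked homologue is there to pair with needs X sites above both-homologue autosomal sites, and they were, by 0.57 (0.39 to 0.72). The same X sites lay below one-homologue autosomal sites, which this hypothesis does not predict. Both comparisons kept X sites of the distal stretch, where signal on the CAST homologue was found. They also took autosomal sites with an H3K4me3 share only, but kept X sites that lack it. Outside the last 1 Mb, CAST X sites with an H3K4me3 share over 0.9 had a median DMC1 of 172, against 104 at all CAST X sites. At HUM X sites these medians were 83.9 and 62.4. How far this filter moved either difference was not measured, so neither decides the question. DMC1 signal alone cannot separate more breaks from longer-lasting ones. The hypothesis was formed and tested on the same data.

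The direction of the asymmetry also mattered differently for the alleles. The gain of CAST over HUM was 0.54 (0.39 to 0.64) at B6-only sites, while at CAST-only sites it was -0.092 (-0.24 to 0.11), an interval that holds 0. The log2 ratio of B6-only minus CAST-only sites was 0.16 (0.01 to 0.26) for CAST and -0.47 (-0.62 to -0.29) for HUM, a difference of 0.63 (0.39 to 0.80). At matched H3K4me3 the values were 0.05 (-0.12 to 0.18) and -0.41 (-0.56 to -0.26). The effect of the X did not differ detectably between the alleles (0.12, -0.12 to 0.34).

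The excess of B6-only over CAST-only sites of the CAST allele by DMC1 share, 11.1 percentage points, was weighed against read mapping. Better mapping to the B6 reference acts on sites of both alleles, but the excess was larger at CAST than at HUM sites by 12.8 points (10.98 to 14.5), which argues against mapping as its whole cause. A candidate explanation is that the CAST strain has lost binding sites of its own PRDM9 allele, most of all the strongest. This needs a larger excess at strong sites, and the excess was 21.9 points in the top 25% of CAST sites by H3K4me3 and -2.03 in the bottom 25%, a difference of 23.9 (21.02 to 26.7), against 2.94 (-0.37 to 6.50) at HUM sites. Sequence of the binding sites was not examined, so loss of motifs remains a hypothesis.

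On the distal X, 39 sites had DMC1 on the CAST homologue, where a male with a B6 X should have none outside the pseudoautosomal region, in which 1 of the 39 lay on the reference. Assignment of reads to the wrong strain along the whole X would show outside the last 1 Mb, but 0.275% (exact interval 0.0334% to 0.992%) of sites there had a share under 0.9. Wrong assignment confined to the distal stretch would leave those sites unchanged, so this test cannot address it. A fault of the DMC1 library would spare H3K4me3, but 87.5% (61.7% to 98.4%) of the 16 sites with both shares also had an H3K4me3 share under 0.9. The median share was still higher for H3K4me3 than for DMC1, both at the 7 sites on PRDM9-independent peaks (0.521 against 0.161) and at the other 9 (0.286 against 0.0831). This difference between the marks stays open. A pseudoautosomal region that reaches further on the CAST Y than on the reference could give this pattern, and it needs 1 position that parts the X, which misplaced 0.260% of 769 sites; that position was itself chosen on these sites. Copies elsewhere in the CAST genome cannot be told apart from it, and more signal per site was expected of them. At the distal sites, which were of other classes, log2 DMC1 differed from the rest of the X by -0.16 (-0.52 to 0.18). Log2 H3K4me3 differed by -2.73 (-3.26 to -1.99). Both intervals resampled single sites, not blocks. The distal sites lie close together, so these intervals may be too narrow. No test placed the CAST sequence on a chromosome.

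The class KO, which no comparison between alleles used, had 84 sites, 22 of them on the X and 13 in the distal 417 kb. On autosomes its median ratio of DMC1 to H3K4me3 was at percentile 86.5 of 10000 random sets matched on H3K4me3.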

How the results depend on the processing

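The settings without sites that overlap PRDM9-independent peaks, without the last 1 Mb of X, against both-homologue sites, within shares of 0.3 to 0.7, with both shares in the same class, with the H3K4me3 share, for the B6-only excess, for the one-homologue gain between alleles, for sites inside genes for the matching of gene length, for sites per Mb of the gene lists and for the position along chromosomes were chosen after seeing the data. Of 86 settings, 81 kept the side of the threshold and, where the main value had passed it, the direction (a 95% interval without 0, the central 95% of random lists, or the exact interval of a share), and so did all 330 values with a chromosome left out. The exceptions were these. Against one-homologue autosomal sites the X ratio was lower, at -0.57, and the cause was not tested. The CAST share of sites was 60.2% in the stronger 50% by DMC1. Selection on DMC1 raises this share, because median DMC1 was higher at CAST sites (83.2) than over all sites (62.1). The list of long neuronal genes reached percentile 99.96 with length matched in 50 bins. The length of those random lists was not recorded, so the cause was not tested. The one-homologue gain of CAST over HUM, 0.26, turned to -0.092 at CAST-only sites and -0.078 there at matched H3K4me3, both with intervals that hold 0, and was 0.17 at matched H3K4me3 and 0.54 at B6-only sites; the cause was not tested. The gain at one-homologue sites ran from 0.77 to 1.23 over 12 settings. The CAST minus HUM difference in log2 ratio ran from 0.24, without the lowest 25% of DMC1, to 0.42 over 8. In DMC1 this difference ran from 0.54 to 0.73 over 6 and in H3K4me3 from 0.21 (means of log2 values) to 0.34 over 6. The correlation ran from 0.595, without the lowest 25% of H3K4me3, to 0.770. The B6-only excess of CAST over HUM rose from 12.8 to 24.6 points in the stronger 50% of sites and was 6.62 with the H3K4me3 share, and the difference in median share of 0.0539 became 0.181 with signal-weighted means, 0.0943 in the stronger 50% and 0.0247 for H3K4me3. The percentiles of gene lists, whose main values were not past the threshold, crossed 50 in these settings: that of the long neuronal genes was 13.99 for sites per Mb, against 78.5 for the count, that of the meiotic list 70.1 without chromosome 9, of the axis list 53.6 without chromosome 3 and of the spermatid list 37.1 without chromosome 15. The pseudocounts of 3.75 and 0.0851, named beforehand as the starting point, gave 1.07 for the one-homologue gain and 0.43 for the X. Leaving out zeros removed no site, tests nothing and is not counted. Not run were minimums of 5 and 20 reads for a B6 share, the distances of 500 bp and 2 kb to transcription starts and the motif windows of 50 and 200 bp. The depth behind the shares was unknown, so how far it limits them was not measured.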

Other observations

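The gene families, the position along the chromosomes and the relation to gene density below were chosen after seeing the data. The chemosensory receptor families held few sites for their length. The 355 vomeronasal receptor genes, which detect pheromones, held 16 sites with 5 kb flanks against 73.4 on average in random lists of similar gene length, and the 1110 olfactory receptor genes held 40 against 72.8. Both counts were at percentile 0 of 10000 random lists. Among 12 families, the protocadherins (77 sites against 117) and the Zfp zinc finger genes (184 against 230) were also low, at percentiles 0.065 and 0.19. The glutamate receptor genes (72 against 98.7) were just past the limit of the central 95%, at percentile 2.41. Of random lists of 20 genes 9.5% fell past that limit, and no correction for the number of families was made. The other 7 families, among them the ribosomal protein genes (18 against 11.7, percentile 95.8), were inside the central 95%. A site in the span or flanks of several genes of a family was counted once for each gene. How many sites this repeated was not recorded, so a count need not be a number of distinct sites. Genes of a family lie in clusters, so they are not independent, and families with near-identical copies are hard to map. The gene with the most sites was Mid1 with 43, followed by Auts2 with 28 (chromosome 5, 131437333 to 132543220) and Arhgap26, Asic2 and Lrmda with 21 each.

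DMC1 per H3K4me3 changed along the chromosomes. With each autosome in 10 equal parts up to its last site, the median log2 ratio was highest in the first part, next to the centromere, at 3.0. It was lowest in parts 5 to 8, at 2.44 to 2.49, and lay between in parts 2 to 4 (2.64 to 2.71), 9 (2.53) and 10 (2.65). Median DMC1 in the first part was 59.7, inside the 56.0 to 64.9 of the other parts, while median H3K4me3 was 8.86 against 11.2 to 12.7. The difference between the first part and parts 5 to 8, the highest set against the lowest, was 0.52 (95% interval 0.40 to 0.63), with the same direction on 17 of 19 autosomes. At matched H3K4me3 it was 0.50 (0.37 to 0.64), on 15 of 19. Among both-homologue sites it was 0.51 (0.37 to 0.64) for CAST and 0.42 (0.27 to 0.63) for HUM. The share of HUM sites in the last part exceeded that in the rest by 2.19 points (-0.02 to 4.31), an interval that holds 0.

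Over the 19 autosomes the median log2 ratio tended to be lower where coding genes were denser. It was highest on chromosome 3 (2.93, with 6.22 genes per Mb) and lowest on chromosome 11 (2.40, with 13.2), but it was 2.51 both on chromosome 1 (6.16) and on chromosome 7, the densest (13.98). Pearson's r was -0.646 (two-sided permutation test, p = 0.00285, adjusted 0.00855) and Spearman's rho was -0.728 (p = 0.00064, adjusted 0.00192), with 3 relations tested and 100000 permutations. Without chromosomes 7 and 11, the farthest from the median density, r was -0.596. Chromosome length showed r of -0.182 (permutation p = 0.457), and the share of HUM sites against gene density 0.365 (permutation p = 0.125). Chromosomes are parts of the same libraries, not independent samples.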
